A study of Caenorhabditis elegans with 2 samples.

How the data were processed

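The series measured where ISW-1, the catalytic subunit of ISWI-type chromatin remodelling complexes in Caenorhabditis elegans, was found along the genome by ChIP-seq. Per the labels, the animals carried an integrated transgene with isw-1 fused to an EGFP, TY1 and FLAG tag together with a rescuing copy of unc-119, and the precipitation used an antibody against GFP. Whole L1 larvae at 6 hours were collected after synchronisation by bleaching and starvation, and chromatin was sheared by sonication. The labels give 2 biological replicates of this 1 condition, so no conditions could be compared and the replicates were compared with each other.

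The authors deposited 8 peak lists on the ce11 build. Per the notes deposited with the samples, each replicate has a list of peaks ranked by the irreproducible discovery rate (IDR) and a thresholded list, and the whole series has 2 ranked lists, a thresholded list and a conservative thresholded list, these last derived from both replicates' alignments. The aligner, the peak caller, their versions and the control used in peak calling are not given in the sources used here, although the labels name a possible control experiment. The lists have no header. From the layout of their columns, the score deposited with each peak is a whole number of at most 1000, the signal value deposited with each peak is the enrichment that the authors' peak caller gave it, and the deposited −log10 columns hold the q value, which was not used, and in the ranked lists the local and global IDR. Signal values belong to the authors and were used only to describe, rank or filter peaks within a list. On the files, every peak of the 4 thresholded lists was found in a ranked list and had a global IDR of at most 0.00997, which fits a threshold of 0.01. Which ranked list belongs to the conservative list was found from identical intervals. A further 16 columns of the series' ranked lists hold values per sample that could not be tied to a replicate and were not used. The signal tracks and alignments were not analysed here. Peak lists carry no read counts, so the depth of each sample is unknown and no interval for counting reads could be given. Intervals on shares of genes or peaks are 95% Wilson intervals and cover only the number of genes or peaks.

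The conservative thresholded list was the main set. Peaks were compared with the genome sequence of the same build (WBcel235, which is ce11) and with Ensembl release 115 gene models. A protein-coding gene was called bound when a summit lay from 1000 bp upstream to 500 bp downstream of its outermost annotated start, and a summit could count for several genes. Summits were sorted into the first class that applied among promoter window, 5′ UTR, coding exon, 3′ UTR, intron and intergenic. Shares were compared with 1000 circular shifts of the summits within chromosomes, for which the smallest two-sided p is 0.0020. Overlap between peak sets needed at least 1 bp and was computed in Python, and bedtools gave the same counts. Where several peaks overlapped one peak, the highest signal was taken.

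Before the data were examined, 38 gene lists and 13 sequences were fixed. Lists were tested with a two-sided Fisher's exact test against all other protein-coding genes (for classes of non-coding genes and pseudogenes, against all protein-coding genes), with Benjamini-Hochberg adjustment over the 38 lists and a threshold of 0.05. In all, 18 listed symbols matched no gene name. Lists overlap in part (lin-53 stands in 2 of them), and divergent genes can share a summit, so genes are not independent. GC content within 100 bp of each summit was compared with both flanks 400 to 600 bp away by 100000 sign flips, whose smallest p is 1e-05. The presence of each sequence on either strand was compared by an exact McNemar test with 1 flank of equal length per peak, its side drawn at random, because both flanks together hold more sequence than the summit window. Named genes followed a rule fixed before the data were examined. It took isw-1, unc-119 and the members of the NURF and ISWI list. It also took the 25 protein-coding genes with the highest signal that had a summit in the window in the conservative set and in both replicates' own sets. From each list it took up to 4 bound members with the highest signal, or the first 2 in alphabetical order where none was bound. Peaks outside promoter windows were to be named only among the 5 highest, and none of these lay outside. One peak among the bound members of the chemoreceptor list is not reported here. Genes and peaks outside this rule are named as chosen after their values were seen.

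Alternatives tried were the other thresholded list, the 1071 peaks of higher signal, each replicate's own list, narrower and wider promoter windows, the start of any transcript, assignment of a summit to the nearest start alone (still within the window), circular shifts or a test stratified by chromosome in place of Fisher's test, uniform placement, other overlap rules, a window of 50 bp and unbound gene starts as the control for sequence. Chosen after seeing the data were a rotation of bound labels along gene order, the peaks found in both replicates' own sets and unbound genes at matched offsets.

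The list test and the promoter test were tested on simulated data. With 19973 genes of which 10% were bound, the list test called 99.5% of lists of 20 or more genes whose members were bound at 50%, 74.9% of those bound at 30% and 1.68% of those bound at the background rate, over 100 simulations. Genes were drawn as bound independently of each other, so these rates do not cover shared summits or neighbouring genes bound together. The promoter test, on 2000 simulated summits and 200 shifts, called 20 of 20 simulations (100%) with 10% of summits planted in promoter windows and 5% of those with none planted. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.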

Results

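ISW-1 binding was measured by ChIP-seq in whole L1 larvae of Caenorhabditis elegans that expressed an ISW-1 protein tagged with GFP, in 2 biological replicates of a single condition. The conservative set of reproducible peaks held 2143 peaks, which covered 642716 bp or 0.641% of the nuclear genome (ce11). The replicates' own thresholded sets held 2090 peaks in replicate 1 and 1756 peaks in replicate 2. Signal values in the conservative set ran from 37.5 to 2624 with a median of 189, as given by the authors. Sequencing depth is unknown because the lists carry no read counts.

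The first comparison asked how far the replicates found the same sites. Of the peaks of replicate 2, 87.4% (1534) overlapped a peak of replicate 1, and 74.7% (1561) of the peaks of replicate 1 overlapped one of replicate 2. Shifting the peaks within chromosomes gave a mean of 1.02% and at most 1.82% (permutation p = 0.0020, the smallest possible). Across shared peaks the authors' signal values correlated with a Spearman rho of 0.859 and, on the log2 scale, a Pearson r of 0.862. Peaks are not independent replicates. Of the 100 highest peaks of replicate 1, 87 were among the 100 highest of replicate 2. The 529 peaks that only replicate 1 passed had a median signal of 77.4, against 158.5 for its shared peaks, and 476 of them (89.98%) overlapped a peak of replicate 2's full ranked list. The 222 peaks that only replicate 2 passed had a median of 50.1 against 92.4, and 201 (90.5%) overlapped a peak of replicate 1's ranked list. Of the conservative peaks, 1538 (71.8%) overlapped both replicates' own sets and 182 overlapped neither.

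**Figure D1:**
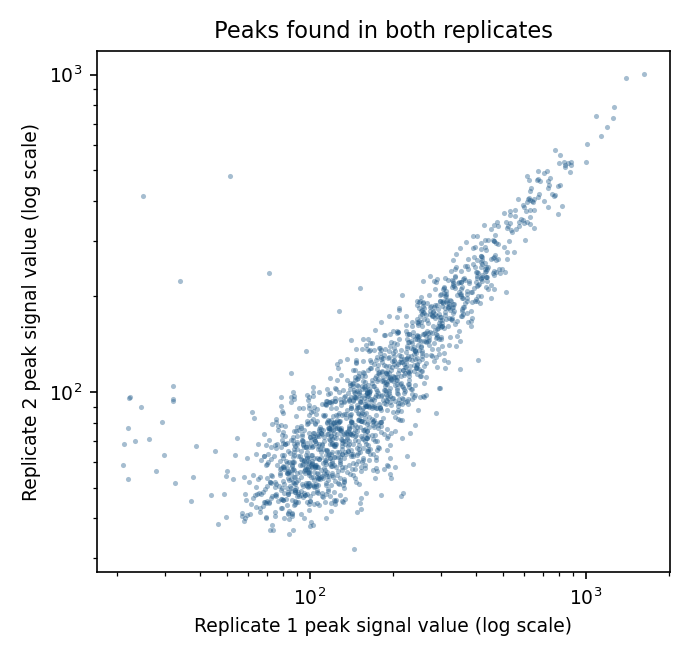
Each point is a replicate 1 peak that overlapped a replicate 2 peak (n = 1561), with the authors' signal value in replicate 1 on the x axis and the highest overlapping replicate 2 value on the y axis, both on log scales. Points follow a rising band (Spearman rho 0.859), and a small group with low replicate 1 values lies above it. Several of that group lie next to a stronger replicate 1 peak and carry the same replicate 2 value as that peak.

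The highest ISW-1 peak (III:1618954-1619310, signal 2624 in the conservative set, 1622 in replicate 1 and 1001 in replicate 2) lay in the divergent promoter of hsp-60, the mitochondrial chaperonin gene, and Y22D7AL.10. Its summit was 598 bp upstream of hsp-60 and 215 bp upstream of Y22D7AL.10. Next came rpl-3 (III:3867398-3867740, signal 2378), rpl-20 with Y17G9B.5 (IV:4749904-4750237, 2046) and rpl-35 (III:7854496-7854858, 1977), whose rpl genes encode proteins of the large ribosomal subunit. The peak of cdc-48.1, which encodes an AAA ATPase of protein quality control, had a signal of 1868 (II:10563421-10563732). Peaks at tasp-1 with K01G5.10 (1832), mog-4 (1776) and C47E8.4 (1590) followed. The rest of the 25 highest genes were rps-18 with sec-61.A, ints-4, rpl-15 with K11H12.8, rpl-12 with lin-54, rps-19 with hsr-9, egl-30 with C53H9.4, cct-8 with Y55F3AR.2, and ska-3 (which shares its summit with rps-12), with signals from 1538 down to 1351. All 25 had a summit in the promoter window in both replicates' own sets, as the rule for naming them required.

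ISW-1 summits were concentrated just upstream of gene starts. In all, 1418 summits (66.2%) lay in the promoter window of a protein-coding gene, against 26.0 ± 0.964% (SD over 1000 shifts) of shifted summits, which is 2.54-fold more (permutation adjusted p = 0.0024). Introns held 14.6% against 29.1%, intergenic sequence outside promoter windows 18.3% against 24.0%, and 3′ UTRs 0.233% against 2.32% (permutation adjusted p = 0.0024 for each). Coding exons outside promoter windows held 5 summits, or 0.233%, against 17.97% of shifted summits (permutation adjusted p = 0.0024). The share in 5′ UTRs, 0.513%, was close to the 0.613% of shifted summits (permutation adjusted p = 0.69). Of all summits, 1680 (78.4%) were upstream of the nearest gene start, and the median position was 177 bp upstream. Of the 1645 summits outside genes, 935 (56.8%) lay between divergent genes, against 34.4% of shifted summits, and 45 (2.74%) between convergent genes, against 11.1% (permutation p = 0.0020 for both). Tandem neighbours flanked 40.4%, against 54.5%.

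**Figure D2:**
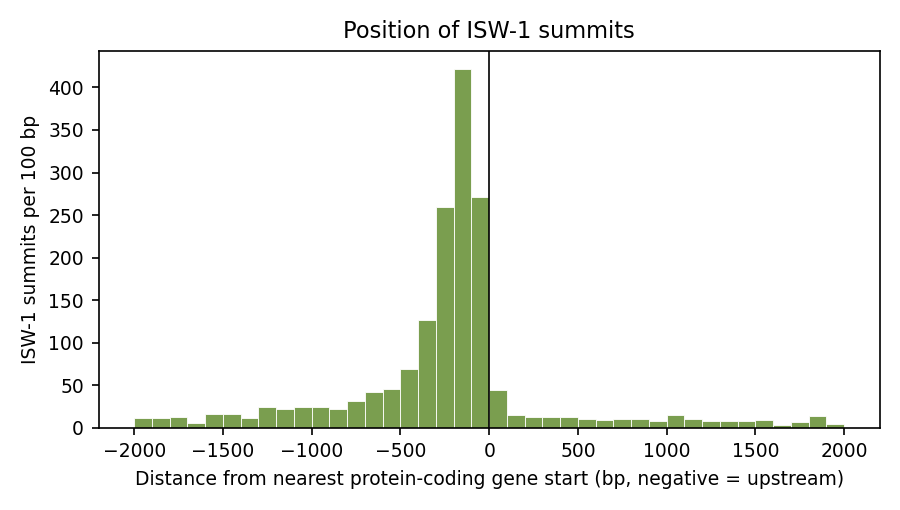
Bars count conservative ISW-1 summits per 100 bp (y axis) by distance from the nearest protein-coding gene start (x axis, bp, negative upstream), for the 1702 summits within 2000 bp. The tallest bar, 422 summits, is 100 to 200 bp upstream.

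Peaks with higher signal were more often at promoters. From the lowest to the highest quartile of signal, the promoter share was 53.5%, 59.5%, 72.9% and 78.7% (95% Wilson intervals 49.3 to 57.7% for the lowest and 75.1 to 82.0% for the highest). Across peaks, signal and distance to the nearest gene start had a Spearman rho of -0.20 (permutation p = 1e-05, the smallest possible). Among the 1071 peaks of higher signal alone, rho was -0.051 (permutation p = 0.096).

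ISW-1 was bound at 1997 of 19973 protein-coding genes (10%), against a mean of 620 under shifts, and ribosomal protein genes had the highest share of the lists. Of the summits at bound genes, 59.4% counted for 1 protein-coding gene and 37.7% for 2. A signal given below for a gene is therefore not always that gene's own. Of 79 ribosomal protein genes, 69 were bound (87.3%, 95% Wilson interval 78.2 to 93.0%; Fisher's exact test, adjusted p = 3.4e-57), led by rpl-3, rpl-20, rpl-35 and rps-18. The shares in the replicates' own sets were 86.1% and 84.8%. Translation factors were bound at 23 of 39 genes (59.0%, Fisher adjusted p = 4.3e-13), among them iff-2 (signal 1348), eef-1A.1 (1157) and eif-3.C (1018). Pre-mRNA splicing genes were bound at 22 of 38 (57.9%, Fisher adjusted p = 2.2e-12), led by prp-19 (907) and the Sm protein genes snr-4 (737) and snr-1 (532). Proteasome subunit genes were bound at 19 of 33 (57.6%, Fisher adjusted p = 9.0e-11), with rpn-3 highest at 1097, a summit shared with hsp-110. Aminoacyl-tRNA synthetases did not pass, with 7 of 32 (21.9%, Fisher adjusted p = 0.054), led by ears-2 and mars-1, but passed in the other thresholded list (0.022).

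Genes of mitochondria and of protein folding were also bound more often than other genes. Oxidative phosphorylation genes were bound at 21 of 46 (45.7%, Fisher's exact test, adjusted p = 2.2e-09), led by cox-5A (signal 1206), cox-5B (725) and the ATP synthase genes atp-1 (1002) and atp-2 (528). Mitochondrial ribosomal proteins were bound at 22 of 66 (33.3%, Fisher adjusted p = 6.1e-07), with mrps-7 at 760 and mrpl-28 at 683. Of 34 heat shock and folding genes 16 were bound (47.1%, Fisher adjusted p = 1.2e-07), including the chaperonin subunit genes cct-8 (1353) and cct-1 (1193), hsp-1 (1225) and hsp-110 (1097, the same summit as for rpn-3). The mitochondrial unfolded protein response list had 9 of 23 bound (39.1%, Fisher adjusted p = 0.00049). Its bound members with the highest signal were hsp-60, the chromatin regulators cbp-1 (1029) and jmjd-1.2 (645), and the import receptor gene tomm-20 (533). With circular shifts in place of Fisher's test the last list had an adjusted p of 0.19, and with rotation of bound labels 0.0030.

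Several lists of chromatin and cell cycle genes passed as well. SynMuv genes, which antagonise vulval fates, were bound at 14 of 29 (48.3%, Fisher's exact test, adjusted p = 5.5e-07), among them the DRM complex genes lin-54 (signal 1376), lin-9 (951), lin-53 (905) and lin-35 (721). The lin-54 summit was 364 bp upstream of lin-54 and 29 bp upstream of rpl-12. The summits of lin-53 and lin-35 also counted for 2 genes each. Other chromatin regulators were bound at 16 of 40 (40%, Fisher adjusted p = 1.4e-06), with cbp-1, jmjd-1.2, ash-2 (492) and mrg-1 (439) highest. Cell cycle and replication genes were bound at 11 of 39 (28.2%, Fisher adjusted p = 0.0023), led by cdc-48.1, pcn-1 (984) and cdc-6 (464). Under circular shifts the adjusted p was 0.056 for the other chromatin regulators and 0.21 for the cell cycle genes, and under rotation of bound labels 0.00058 and 0.019.

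The genes carried by the transgene gave little signal. At isw-1 (III:6703988-6710100, minus strand) a promoter peak with signal 127.9, 132 bp upstream of the gene start, was in the conservative set at rank 1629 by signal. It was in neither replicate's own thresholded set nor in the other thresholded set, each of which held 1 peak at the gene outside the promoter window. At unc-119 (III:10902641-10908935) no thresholded list held a peak. Among the NURF and ISWI genes, 3 of 6 were bound (50%; Fisher's exact test, adjusted p = 0.026). lin-53, a histone-binding subunit gene, had a signal of 904.9 and a peak in every thresholded set, whereas nurf-1 had a promoter peak of 127.7 in the conservative set and, among the replicates' sets, in replicate 2 alone. Inside nurf-1 both replicates' sets held a peak, named after its values were seen (II:14399702-14399868, signals 219.6 and 99.5). athp-2, pyp-1 and rba-1 had no thresholded promoter peak. The call for these 6 genes did not hold in the other thresholded list (odds ratio 1.76, adjusted p = 0.53) or in either replicate's own list (adjusted p = 0.52 and 0.13, Fisher's exact test). It was also lost under circular shifts (permutation adjusted p = 0.56) and under rotation of bound labels along gene order (0.13).

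Several gene families and the intestine markers were rarely bound. Chromatin came from whole larvae and no expression values were used. Differences in share between lists can therefore not be told apart from differences in tissue or expression. Chemoreceptor genes were bound at 10 of 1364 (0.733%, Fisher's exact test, adjusted p = 9.4e-49), among them sri-5 (signal 487). C-type lectins were bound at 2 of 240 (0.833%, Fisher adjusted p = 2.5e-08), namely clec-104 (190.1) and clec-53 (131.9). F-box genes of the A, B and C families were bound at 8 of 322 (2.48%, Fisher adjusted p = 7.2e-07), and nuclear hormone receptors at 8 of 269 (2.97%, adjusted p = 3.4e-05), with nhr-47 highest at 521. Cuticle collagens were bound at 7 of 176 (3.98%, Fisher adjusted p = 0.0096), led by col-38 (744). UDP-glucuronosyltransferases had 1 of 67 bound (ugt-50, signal 98.4, Fisher adjusted p = 0.022), cytochrome P450s 0 of 74 (adjusted p = 0.0015), and intestine markers 0 of 40, such as acdh-1 and act-5 (adjusted p = 0.048). Under circular shifts the nuclear hormone receptors (permutation adjusted p = 0.21), collagens (0.39), UDP-glucuronosyltransferases (0.56), cytochrome P450s (0.51) and intestine markers (0.76) did not pass, whereas under rotation of bound labels along gene order, chosen after seeing the data, the receptors (0.0096), collagens (0.019) and cytochrome P450s (0.019) passed. Shifted summits hit 620 genes on average, against 1997 observed, so small lists often had few or no hit genes in shifts. Cytochrome P450s and intestine markers had 0 bound genes, the lowest count possible, so the shifts could not have called them. For the intestine markers the call was also lost in the other thresholded list and in replicate 2's own list (Fisher's exact test, adjusted p = 0.15 and 0.30).

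Lists of other tissues and signalling genes did not pass Fisher's exact test. Heterochronic genes had 4 of 14 bound (28.6%, Fisher adjusted p = 0.064), with nhl-2 (signal 1070), lin-66 (379), lin-46 (290) and lin-28 (205). Insulin and nutrient signalling genes had 4 of 26 (Fisher adjusted p = 0.37), namely rheb-1 (375), hlh-30 (165), daf-16 (164) and akt-2 (93.3). Neuron markers had 7 of 48, muscle markers 4 of 39, germline genes 3 of 43, core histones 10 of 72 (18.06% in replicate 1's own set and 5.56% in replicate 2's), ceh homeobox genes 3 of 63, hlh genes 2 of 25 and insulin-like peptides 1 of 39 (ins-39), with Fisher adjusted p from 0.22 to 1. Hypodermis markers (0 of 23, such as ajm-1 and ceh-16) and major sperm proteins (0 of 31, such as msp-10 and msp-113) had no bound member, with Fisher adjusted p = 0.21 and 0.096.

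**Figure D3:**
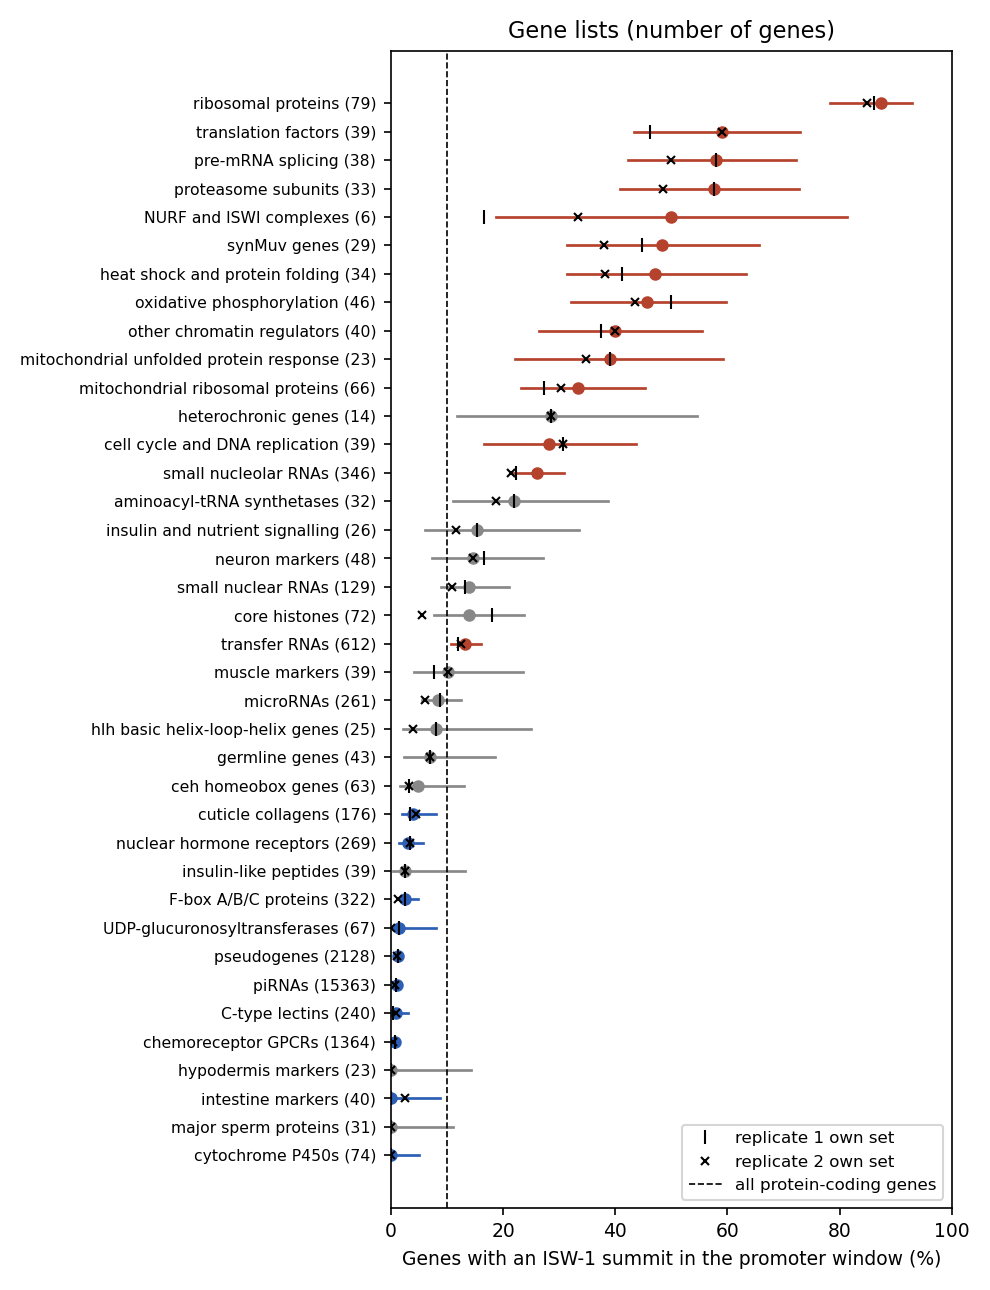
Points give the share of each list's genes with a conservative ISW-1 summit in the promoter window (x axis, percent), with 95% Wilson intervals as lines and the number of genes in brackets. Red and blue mark lists bound more or less often by Fisher's exact test at an adjusted p under 0.05, grey the others; ticks and crosses give each replicate's own set, and the dashed line is the 10% of all protein-coding genes.

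Among non-coding genes, small nucleolar RNA genes were bound at 90 of 346 (26.0%, Fisher's exact test against protein-coding genes, adjusted p = 3.3e-16). For 37 of the 90 a summit lay outside the promoter windows of protein-coding genes, and the summits of the others lay within them, as for C06A1.9 and cdc-48.1. These 37 are 10.7% of the 346 genes, close to the 10% of protein-coding genes bound. The excess can therefore not be told apart from binding at neighbouring protein-coding promoters. Transfer RNA genes were bound at 81 of 612 (13.2%, Fisher adjusted p = 0.021), led by C18A11.t2 on X (signal 621). For 64 of the 612 (10.5%) a summit lay outside the promoter windows of protein-coding genes. Small nuclear RNA genes did not pass (18 of 129, 13.95%, Fisher adjusted p = 0.19), but 3 spliced-leader genes of the SL2 type headed them, with sls-2.4 at 1207, sls-2.1 at 1187 and sls-2.2 at 1040. MicroRNA genes did not pass (22 of 261, Fisher adjusted p = 0.51), with cel-mir-5549 highest, at the same peak as given above for eef-1A.1. Pseudogenes (28 of 2128, 1.32%, Fisher adjusted p = 7.7e-56) and piRNA genes (159 of 15363, 1.03%; circular shifts, permutation adjusted p = 0.011) were rarely bound, although the pseudogene K08F11.6 had a signal of 1432. The transfer RNA call was lost under circular shifts (permutation adjusted p = 0.32) and its direction turned among the 1071 peaks of higher signal (odds ratio 0.806, Fisher adjusted p = 0.40).

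Chromosomes differed in how densely they were bound. Chromosomes III and I carried 30.5 and 29.0 summits per Mb and had 16.44% and 14.9% of their protein-coding genes bound. Chromosome V carried 14.1 per Mb with 6.21% bound, and X carried 16.6 per Mb with 5.82% bound. On X, 159 genes were bound, against 10.7% of autosomal genes (1838; odds ratio 0.518, Fisher's exact test p = 9.3e-17). The 295 summits of X were 0.779 of the number its length would give (exact binomial test, p = 1.2e-06), but 1.01 of the number its protein-coding genes would give (exact binomial test, p = 0.90). Within autosomes, 39.3% of summits lay in the middle part of the chromosome, 1 of 3 equal lengths, which was 1.18-fold the shifted share (permutation p = 0.0040). Genes there were bound at 11.4% against 10.2% elsewhere (odds ratio 1.13, Fisher's exact test p = 0.016), a call that was lost among the 1071 peaks of higher signal (odds ratio 1.097, p = 0.14).

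**Figure D4:**
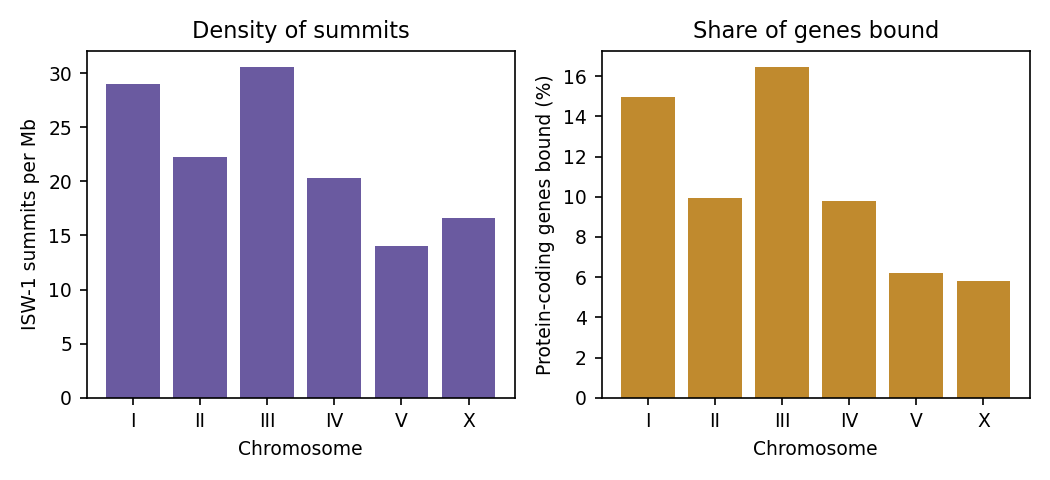
Bars give, for each chromosome, the conservative ISW-1 summits per Mb (left) and the percent of protein-coding genes with a summit in the promoter window (right). Chromosomes III and I are highest in both panels, while V has the lowest density (14.1 per Mb) and X the lowest share of genes bound (5.82%).

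ISW-1 summits were richer in GC than their surroundings and carried particular short sequences. GC content within 100 bp of the summit was 43.95 ± 7.36% (SD over 2143 peaks) against 36.5 ± 5.63% in the flanks, higher at 74.8% of peaks (permutation p = 1e-05, the smallest possible). TGCGTCTC was present at 16.38% of summits and 0.980% of flanks, a ratio of 16.7 (exact McNemar test, adjusted p = 8.6e-81). The GA repeat GAGAGAGA was present at 12.55% against 1.26% (exact McNemar adjusted p = 5.4e-51), the E2F-like site GCGCGAAA at 3.55% against 0.513% (9.1e-13) and GGGCGG at 10.4% against 3.73% (5.2e-17). The B-box sequence GTTCGAATC was found at 14 summits and 3 flanks (exact McNemar adjusted p = 0.017), but not in the other thresholded list (0.26), the 1071 peaks of higher signal (0.69) or either replicate's own list (0.071 and 0.056). Sequences less frequent at summits were the GATA site TGATAA (6.72% against 17.5%, exact McNemar adjusted p = 6.4e-27), TTTGAA (33.6% against 45.6%, 5.2e-15), TAATTA (4.95% against 10.5%, 2.0e-11), TTTTTTTTTT (2.99% against 5.18%, 0.00066) and CCAAT (30% against 34.6%, 0.0019, but 0.090 in replicate 2's own list). TGATAA, TTTGAA, TAATTA and TTTTTTTTTT are rich in A and T, and no control was matched for GC content. A loss of these particular sites can therefore not be told apart from the base composition of summits. The same holds for the gain of GGGCGG, which contains only G and C. How far base composition adds to the other gains was not tested. CACGTG, TTCCCGCC and TGACTCA did not pass (exact McNemar adjusted p = 0.15, 0.063 and 0.39).

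**Figure D5:**
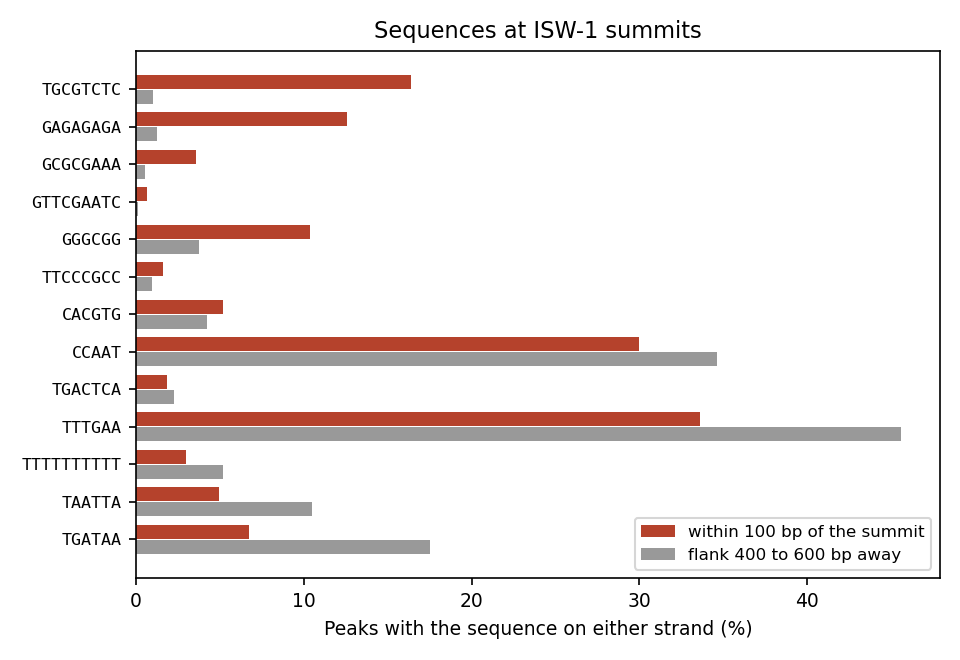
Bars give the percent of 2143 peaks with each sequence on either strand, within 100 bp of the summit (red) and in an equally long flank 400 to 600 bp away (grey). TGCGTCTC (16.38% against 0.980%) and GAGAGAGA (12.55% against 1.26%) show the widest gaps in favour of summits.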

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

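The test of replicate signal in this part was chosen after related values were seen, and the genes and peaks named here were chosen after their values were seen. There were 17 peaks in the ranked list of the series that passed the IDR threshold and yet were missing from the conservative set, a signal in data that the comparisons above do not use. The highest of them, at X:15811038-15811136 and 6937 bp from the nearest protein-coding gene start, had a signal of 1297, more than most peaks that were kept. Among the windows within 100 bp of these summits, a median of 82.5% of 31-mers occurred more than once in the genome, and 14 of the 17 windows had at least 50% of such 31-mers, whereas the mean share was 72.5% at these, 10.3% at kept summits outside promoter windows without a GA repeat and 8.73% in the whole genome. This is consistent with removal of peaks in repeated sequence, a step that no source used here records. The exceptions included the peaks next to bet-1 and cts-1, which held no repeated 31-mer. The ratio of replicate 1 to replicate 2 signal lay outside the central 95% of the conservative set (1.06 to 2.94) at 8 of the 17 (47.1%), each time below it, and 1 peak without a replicate 1 peak was counted as inside. The share is just under the bound of 50% set for this explanation. It would reach the bound as 8 of the 16 peaks with a ratio, and pass it if the peak without a ratio were counted as outside. A signal carried by one replicate therefore stays open. Several of the 17 peaks lie next to each other and are not independent. The design has 1 condition, so no biological explanation was tested.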

How the results depend on the processing

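The design has 1 condition, so no paired analysis was possible because there is no second group to pair with. Of 657 comparisons of a result with an alternative, 588 kept their side of the threshold or, for counts, stayed within 1.5-fold. Results that passed in neither setting were not compared for direction. The fold for promoter windows ran from 1.89 to 4.10 over window sizes, peak sets and null models, with p at the smallest possible value in each, and the fold for divergent neighbours from 1.62 to 1.75. The fold for the middle of autosomes ran from 1.15 to 1.198, and the GC difference from 6.83 to 11.6 points. The overlap of replicate 2 with replicate 1 ran from 76.1% to 87.4%, and that of replicate 1 with replicate 2 from 64.1% to 83.3%. Among the 1071 peaks of higher signal, the correlation of signal with distance fell to -0.051 (permutation p = 0.096, against -0.18 to -0.20 in the other peak sets), the number of bound genes was 1201, and the odds ratio for transfer RNA genes turned to 0.806 (Fisher's exact test, adjusted p = 0.40). With circular shifts in place of Fisher's test, 9 lists were bound more often and 5 less often, in place of 14 and 10. Shifted summits hit 620 genes on average, against 1997 for the observed ones, so small lists had little room to pass as bound less often. With the bound labels rotated along gene order instead, an alternative chosen after seeing the data, 11 of 32 protein-coding lists were bound more often and 6 less often, against 12 and 8 by Fisher's test. The ratio for X turned from 0.779 to 1.01 with gene starts in place of length (exact binomial test, p = 0.90). The ratio for TGCGTCTC ran from 8.34 against unbound genes at matched offsets to 42.7 within 50 bp of the summit, that for GAGAGAGA from 3.69 at matched offsets to 9.96, and that for GCGCGAAA from 4.29 without replicate 1 to 9.4 within 50 bp. The comparison at matched offsets used only the 1418 summits in promoter windows. Against flanks, the ratios at those summits were 12 for TGCGTCTC and 7.5 for GAGAGAGA. The ratio for GTTCGAATC turned to 0.5 within 50 bp of the summit. It lost its call in 5 further alternatives (adjusted p from 0.056 to 0.69) and CCAAT in 2 (0.090 without replicate 1 and 0.054 within 50 bp), while TTCCCGCC passed in 4, CACGTG in 2 and TGACTCA in 1. The odds ratio for genes in the middle of autosomes lost its call among the 1071 peaks of higher signal (1.097, Fisher's exact test, p = 0.14). The causes of these changes were not tested. Single lists lost their call in 37 of 450 comparisons and gained one in 10 (heterochronic genes in 4, aminoacyl-tRNA synthetases in 2), and single sequences in 7 and 7 of 91. The NURF and ISWI, intestine, transfer RNA and UDP-glucuronosyltransferase lists account for most of the losses. Unknown depth limits what an absent peak says, since a site without a peak can lie below the reach of either library.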

Other observations

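Chosen after the data were examined were the tests of this paragraph and the next, the comparisons inside and outside promoter windows of the GA repeat, of TGCGTCTC and of X, and the tests by nearest gene start. Of the spliced-leader genes, 5 of 18 of the SL2 type were bound (sls-2.1, sls-2.2, sls-2.4, sls-2.8 and sls-2.9) and 0 of 12 of the SL1 type, a difference that was not tested. Peaks in repeated sequence may be missing from the set, and repeated sequence at these genes was not measured. The difference can therefore not be read as a preference of ISW-1. Bound ribosomal protein genes had a median signal of 485, against 224 for the other bound genes (permutation test over 24 lists, adjusted p = 0.0048), and no other list passed that test. Their 66 summits held no GA repeat and 4 (6.06%) held TGCGTCTC, against 7.46% and 13.7% of the summits at other bound genes. A summit shared by a ribosomal protein gene and another gene stands in both groups, and these differences were not tested.

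Every 8-base sequence with at least 10 unequal pairs of summit and flank was compared as well, 24758 in all, of which 1972 were more frequent at summits and 1417 less frequent (exact McNemar test, Benjamini-Hochberg adjusted). AGACGCAG led with 17.4% of summits against 1.12% of flanks, and it overlaps GAGACGCA, which is TGCGTCTC read on the other strand. AAACGCGC was present at 7.61% against 0.187%. AAAAATTT had the smallest p among the less frequent ones, at 6.91% against 16.7%. It holds only A and T. The flanks were not matched to the summits for GC content, a limit that also applies to the more frequent sequences. The GA repeat and TGCGTCTC occurred in the same window 91 times (odds ratio 3.17, Fisher's exact test, p = 2.8e-14). Both contain TCTC on 1 strand, so a single stretch can hold both, and the test does not allow for this overlap.

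The GA repeat was more frequent at summits outside promoter windows (22.6%) than inside them (7.40%; Fisher's exact test, p = 1.8e-22). Peaks carried by one replicate do not account for it, since the share overlapping both replicates' sets was 2.42 points higher with the repeat than without it outside promoters (95% bootstrap interval -6.27 to 10.6). Repeated genomic sequence does not either, since the mean share of repeated 31-mers was lower with the repeat, with a difference of -8.17 points (95% bootstrap interval -10.3 to -6.09). Dinucleotide repeats in general remain a candidate explanation, as ACACACAC was also more frequent outside promoter windows (10.8%) than inside (3.88%, Fisher's exact test, p = 2.0e-09). It was 5.2 times as frequent as in flanks outside and 4.23 times inside. Outside, CGCGCGCG was at 18 summits and 0 flanks, although ATATATAT was at 4 and 3. Neither of these 2 differed between outside and inside (Fisher's exact test, p = 0.34 and 0.24). TGCGTCTC, which is no dinucleotide repeat, was also more frequent outside promoter windows (21.9% against 13.5%; Fisher's exact test, p = 1.3e-06). It can overlap a GA repeat, so it is not a fully separate contrast, and no biological explanation was tested.

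Genes on X were bound less often than autosomal genes. The genes of the fixed lists do not account for it by themselves, since the odds ratio was 0.479 without them (5.58% of X genes bound against 10.98% of autosomal genes). Most protein-coding genes, 16518 of 19973, are in no list, so a wider difference in gene content was not tested by this. The distance of X summits from gene starts stays open: 49.2% of X summits lay in promoter windows against 68.9% on autosomes (Fisher's exact test, p = 8.8e-11), and counting only the nearest gene of each summit gave an odds ratio of 0.713 within the promoter window. At any distance it was 0.970 (Fisher's exact test, p = 0.70), a value that the even number of summits per gene fixes near 1, so it decides nothing. Whether the threshold removes weaker X peaks cannot be told apart from a true difference, since the odds ratio with every ranked peak was 0.820, between the bounds set for either outcome, and no biological explanation was tested.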
